A study of Mus musculus with 6 samples.

How the data were processed

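RNA-seq libraries from intestinal organoids of Apc Min mice were compared between 3 control and 3 DM-aKG samples. Per the labels, RNA was extracted with a Qiagen kit and the libraries are of total RNA, with TruSeq SR Cluster V3 kits named for their preparation, which leaves the selection of RNA and the strand open. Per the submitters' processing notes, CASAVA 1.8, HISAT2 2.0.4, Partek (no version given) and the mouse build mm10 were used; which step each tool did, the gene annotation and the treatment of reads that match several genes are not given in the sources used here. The authors deposited a table of RPKM, with 2 decimals, for 24956 genes named by symbol and 6 libraries, and each column was taken to its sample by its title.

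RPKM divides a gene's reads by its length and by the reads of the library, so a few abundant genes that change shift all others slightly, and values near 0 are rounded. The 10 most abundant genes held 7.31% to 7.70% of the RPKM sum in the controls and 6.09% to 6.24% in the DM-aKG libraries. Depth was estimated from miRNA and snoRNA genes of at most 150 bases (lengths from RefSeq), for which a read is worth a large step in RPKM. The depth was chosen to put as many values as possible at 1 read, which was 34 to 55 per library. Of the other values of up to 5 reads (35 to 40 per library), 88.6% to 92.3% came out whole, within 0.05 reads, where evenly spread values would give 10%. Intervals from such depths would cover counting error only, and none is printed.

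Values were analysed as log2(RPKM + 0.5). Genes entered if their mean over all 6 libraries was at least 1 RPKM, which left 10852; 14104 were below, of which 6613 were listed at 0 in every library. A fold change on this scale understates the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), without the replicate number in the model, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes, with calls at an adjusted p under 0.05. Gene lists were tested with camera (preset inter-gene correlation 0.01) where at least 5 members were tested, again with Benjamini-Hochberg adjustment over the 21 lists, beside camera with an estimated correlation and fry, which asks whether the members move on balance in a common direction without comparing them with other genes. For each list the members are also counted with p-values adjusted over the list alone.

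Before the data were examined, the groups, the tests, the lists and the rule for named genes were fixed. The lists covered Wnt targets, Wnt antagonists, stem cell, enterocyte, goblet, Paneth, enteroendocrine, tuft and fetal or regenerative genes, proliferation, the TCA cycle, glutamine and α-ketoglutarate metabolism, dioxygenases, hypoxia and glycolysis, ATF4, cholesterol synthesis, fatty acid oxidation and PPAR, interferon, NRF2 and p53 genes, ribosomal proteins, histones, mitochondrially encoded genes, and markers of fibroblasts and muscle, of immune cells and of endothelial and glial cells. Named genes were the 8 with the largest rise and the 8 with the largest fall among called genes with groups that do not overlap and a mean of at least 3 RPKM in the higher group (clone and gene model names skipped), up to 3 members of each list with the smallest p, and Lgr5, Axin2, Ascl2, Myc, Krt20, Fabp2, Alpi, Muc2, Mki67 and Apc. Other genes are named as examples or because they went against their list, and those were chosen after their values were seen. Every gene described as risen or fallen passed limma with all 3 DM-aKG libraries beyond all 3 controls, unless overlap is stated. Gene positions come from the GENCODE annotation of GRCm38, the assembly that mm10 names; 86 of 87 named genes had a single position there.

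The procedure was tested on simulated values for 10698 genes with the spread of these groups: 26.5% of genes changed by 0.25 on the log2 scale were called, 74.5% at 0.5, 93.9% at 1 and 100% at 2, with 3 false calls among 144, and 0 of 20 lists without a change were called. In it 10506 genes were left unchanged. Noise was drawn independently for each gene, so the simulation cannot show how often the list test errs where members are correlated, as in many of the real lists. Alternatives covered the pseudocount, the filter, median centring, quantile normalization, rescaling to an equal sum per library, the variance model, array weights, the replicate number as a block, a fold threshold and the omission of each library. Leaving out control replicate 2 and DM-aKG replicate 1 together was added after the data were seen, as were families of genes with a common symbol stem. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.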

Results

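RNA was sequenced from intestinal organoids of Apc Min mice, cultures of epithelial cells that grow in medium as closed, budding structures. Apc Min mice carry a nonsense mutation in Apc, a gene whose protein marks β-catenin for destruction and so restrains Wnt signalling, and they develop intestinal tumours. The study set 3 control cultures against 3 treated with DM-aKG, the cell-permeable dimethyl ester of the TCA cycle metabolite α-ketoglutarate. The title of the series poses the question as the effect of α-ketoglutarate on Wnt signalling and differentiation. What the controls received, the dose and the time of treatment are not given in the sources used here. The replicates are called biological, but whether they came from separate mice or from cultures of a single line is not given either. Values are RPKM (reads per kilobase of transcript, scaled by library size) for 24956 genes. The read depth estimated from the smallest values was 32.7 to 34.2 × 10⁶ reads per library, so a gene of 1 kb at 1 RPKM stands for about 32.7 to 34.2 reads, with a counting error of 17.1% to 17.5%. RPKM values summed to 369553 to 374975 in the controls and 358636 to 363467 in the DM-aKG libraries.

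DM-aKG changed a large part of the organoid transcriptome. Anxa1, which encodes the phospholipid-binding protein annexin A1, rose from 7.35 ± 0.181 to 94.2 ± 11.5 RPKM (mean ± SD, n = 3 per group, as throughout), a log2 fold change of 3.59 ± 0.08 (SE; limma, adjusted p = 4.20e-07). Nqo1, a quinone reductase of the antioxidant response, rose from 9.68 ± 0.827 to 120.3 ± 14.0 RPKM (log2 fold change 3.56 ± 0.09; limma, adjusted p = 5.16e-07). Olfm4, a secreted glycoprotein used as a marker of intestinal stem cells, fell from 88.4 ± 12.8 to 8.10 ± 9.24 RPKM, and it fell by 3.91 ± 0.62 on the log2 scale (limma, adjusted p = 0.00141). Ankrd37, a target of hypoxia-inducible factor, fell from 35.1 ± 12.5 to 4.74 ± 1.19 RPKM. Of 10852 genes tested, 3354 were higher and 2679 lower in DM-aKG, together 6033 or 55.6% of those tested. A fold change of at least 1.5 was reached by 764 of the higher and 533 of the lower genes, and a fold change of at least 2 by 291 and 143. In 6967 genes (64.2%) the groups did not overlap, where chance gives 10%. Centring each library on the median of the tested genes turned the balance of calls to 2790 higher and 3340 lower, as many calls rest on small changes. The median over all tested genes then moved from 0.02 to -0.03 on the log2 scale.

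**Figure D1:**
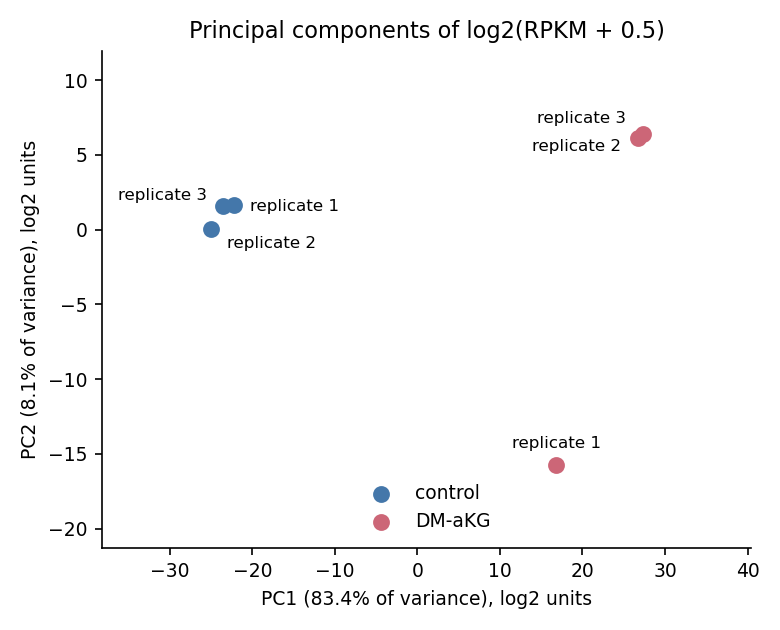
First and second principal components of log2(RPKM + 0.5) over the tested genes, in log2 units, with a point for each of the 6 libraries (control blue, DM-aKG red). The groups lie apart on the first component, which holds 83.4% of the variance, and DM-aKG replicate 1 lies apart from the other treated libraries on the second, which holds 8.1%.

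Libraries of the same group correlated at r = 0.994 to 0.997 (control) and 0.990 to 0.997 (DM-aKG) across genes, and libraries of different groups at 0.957 to 0.971; genes are not independent replicates, so these values only describe the libraries. Within the DM-aKG group, replicate 1 held more RNA of Paneth cell genes, with Defa17 at 329.6 RPKM against 68.5 and 60.2 in replicates 2 and 3. Control replicate 2 had higher levels of some hypoxia-inducible genes, with Adm at 13.6 RPKM against 3.58 and 4.84 in the other controls.

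Beyond Anxa1 and Nqo1, the genes with the largest rises were Prl2c4 (3.27 ± 0.58 log2), the desmosomal cadherin gene Dsg3 (2.99 ± 0.36), the exonuclease gene Trex2 (2.93 ± 0.15), the synaptotagmin gene Syt8 (2.90 ± 0.10), Slc7a11 (2.87 ± 0.08) and Gprc5a (2.81 ± 0.16). Slc7a11, the cystine transporter subunit that feeds glutathione synthesis, rose from 8.16 ± 0.827 to 62.5 ± 5.22 RPKM. Prl2c4 and Dsg3 were higher in DM-aKG replicate 1, at 15.8 and 11.4 RPKM, than in replicates 2 and 3, at 5.48 and 5.76 for Prl2c4 and 3.70 and 3.99 for Dsg3. Prl2c4 was at 1.68 RPKM in control replicate 1 and at 0.06 in each of the other controls, and without control replicate 1 the gene Prl2c4 had a log2 fold change of 3.92. With a pseudocount of 0.1 in place of 0.5 the gene Prl2c4 rose by 4.49, the gene Dsg3 by 3.97 and the gene Trex2 by 3.83, so the order of the largest rises depends on it. Among the largest falls after Olfm4 and Ankrd37 were Defa17, which fell by 2.45 ± 0.58 on the log2 scale, and Defa30, which fell by 2.41 ± 0.69; both encode Paneth cell defensins. The secretory granule gene Sycn fell by 2.33 ± 0.13, the tryptase gene Tpsg1 fell by 2.32 ± 0.15, the colipase gene Clps fell by 2.24 ± 0.10, and the ubiquitin ligase gene Rnf186 fell by 2.22 ± 0.20. Prl2c4, Defa17 and Defa30 belong to families with near-identical copies, among which reads could have been divided in ways the values do not show, so their levels are uncertain. The call of Defa30 (limma, adjusted p = 0.0188) was lost without control replicate 2 (limma, adjusted p = 0.0651) or 3 (0.0554), without DM-aKG replicate 2 (0.0583) or 3 (0.0621), and with no filter on low values (0.0507). Without DM-aKG replicate 1 the log2 fold change was -4.76 for the gene Olfm4, -3.23 for the gene Defa17 and -3.28 for the gene Defa30. On the mouse assembly GRCm38, Anxa1 lies on chromosome 19, 20373428 to 20390944 (minus strand), and Nqo1 on chromosome 8, 107388225 to 107403206 (minus strand). Slc7a11 lies on chromosome 3, 49892526 to 50443614 (minus strand), Olfm4 on chromosome 14, 79984081 to 80023139 (plus strand) and Ankrd37 on chromosome 8, 45996902 to 46005707 (minus strand), all annotated as protein-coding genes.

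**Figure D2:**
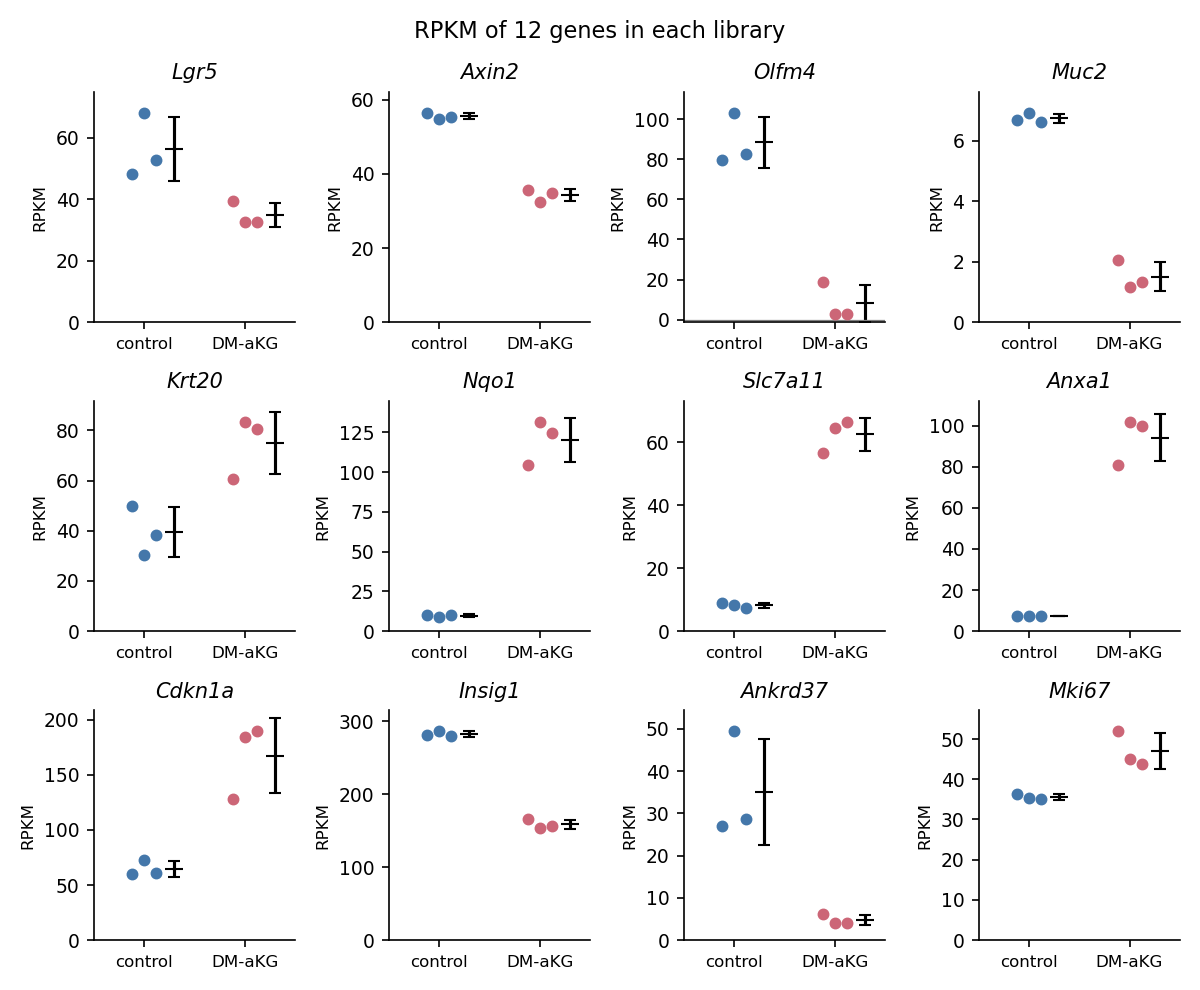
RPKM of selected genes in each library, with a point per library (control blue, DM-aKG red) and the mean with its SD over 3 libraries in black; the vertical axes are linear and differ between panels. All DM-aKG points of Lgr5, Axin2, Olfm4, Muc2, Insig1 and Ankrd37 lie below the control points, and all those of Krt20, Nqo1, Slc7a11, Anxa1, Cdkn1a and Mki67 above them.

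Most tested genes of the intestinal stem cell fell, as did 8 of 16 tested Wnt targets. Axin2, a feedback inhibitor that Wnt signalling induces, fell from 55.5 ± 0.818 to 34.3 ± 1.58 RPKM (limma, adjusted p = 2.70e-05), and it fell by 0.69 ± 0.04 on the log2 scale. Lgr5, the receptor that marks crypt base stem cells, fell from 56.4 ± 10.4 to 34.9 ± 3.93 RPKM (limma, adjusted p = 0.00322). Ascl2, a stem cell transcription factor, fell from 15.6 ± 1.22 to 10.4 ± 0.289 RPKM (limma, adjusted p = 2.64e-04). Of 16 tested members of the Wnt target list (24 listed), 1 was higher, 8 lower and 7 not past the threshold (1 higher and 8 lower adjusted over the list alone). The list median was -0.28 (camera, adjusted p = 0.0175; adjusted p = 0.283 with an estimated correlation). The member that rose was Cd44, which encodes a hyaluronan receptor, from 13.6 ± 0.425 to 25.8 ± 0.733 RPKM. The ephrin receptor gene Ephb3 fell by 1.09 ± 0.06 on the log2 scale, whereas Myc was at 50.8 ± 7.61 RPKM in control and 53.1 ± 1.34 in DM-aKG (limma, adjusted p = 0.550). In the stem cell list, also of 16 tested genes, 2 were higher, 11 lower and 3 not past the threshold (2 higher and 11 lower adjusted over the list alone). The median over the list was -0.68 (camera, adjusted p = 5.32e-04; adjusted p = 0.287 with an estimated correlation). The chloride cotransporter gene Slc12a2 fell from 186 ± 5.91 to 84.5 ± 18.3 RPKM, Prom1 fell from 88.3 ± 2.45 to 53.5 ± 3.84 RPKM, and the 2 that rose were Cd44 and Igfbp4. Both lists share 8 genes, Lgr5, Axin2 and Ascl2 among them, and are not independent. Mmp7, a Wnt target that fell, is also in the Paneth list. Olfm4 stood at 18.8 RPKM in DM-aKG replicate 1 and at 2.94 and 2.59 in replicates 2 and 3. Lgr5 lies on chromosome 10, 115450311 to 115587780 (minus strand) and Axin2 on chromosome 11, 108920349 to 108950783 (plus strand) of GRCm38.

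Among 5 tested antagonists of Wnt signalling, the 4 that were lower were Dact2, Kremen1, Shisa2 and Axin1 (0 higher and 4 lower adjusted over the list alone). Shisa2 had the largest change and fell from 11.4 ± 0.165 to 5.74 ± 0.590 RPKM. The median over the list was -0.27 (camera, adjusted p = 0.0239; adjusted p = 0.321 with an estimated correlation). The list was no longer past the threshold with no filter on low values (camera, adjusted p = 0.213). Apc itself was at 16.1 ± 0.393 RPKM in control and 16.9 ± 1.15 in DM-aKG (limma, adjusted p = 0.286); a total RPKM does not separate the mutant from the normal allele. The other 16 listed antagonists lay below the filter, none above 0.99 RPKM in any library. They were not tested and went both ways. Sfrp5 and Apcdd1, for example, were lower in every DM-aKG library than in every control, and Kremen2 was higher.

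Markers of differentiated cells moved in different directions by cell type. Most tested goblet cell genes fell. Muc2, the main secreted mucin, fell from 6.74 ± 0.161 to 1.51 ± 0.467 RPKM (limma, adjusted p = 5.51e-05). The trefoil factor gene Tff3 fell from 1006 ± 38.4 to 370.2 ± 58.8 RPKM and Fcgbp from 296 ± 18.7 to 127 ± 12.7 RPKM. Atoh1, the transcription factor of the secretory lineage, fell from 4.86 ± 0.520 to 1.82 ± 0.325 RPKM. Of 15 goblet genes tested (18 listed), 0 were higher, 12 lower and 3 not past the threshold (1 higher and 12 lower adjusted over the list alone). Their median log2 fold change was -1.22 (camera, adjusted p = 8.25e-06; adjusted p = 0.321 with an estimated correlation). Clca1, Zg16 and Tspan13, the goblet genes not past the threshold, had log2 fold changes of 0.32, 0.07 and 0.16, with overlapping groups. Paneth cell genes fell as well. Among them, Lyz1, which encodes lysozyme, fell from 323 ± 35.0 to 153 ± 68.5 RPKM, and the lectin gene Itln1 from 973 ± 69.4 to 515 ± 127 RPKM. Among 13 tested (15 listed), 1 was higher, 8 lower and 4 not past the threshold (1 higher and 8 lower adjusted over the list alone). The list median was -1.15 (camera, adjusted p = 0.00314; adjusted p = 0.406 with an estimated correlation). The Paneth gene that rose was the phospholipase gene Pla2g2a, by 2.29 ± 0.40 on the log2 scale. Lyz1 was at 232 RPKM in DM-aKG replicate 1 and at 115 and 113 in replicates 2 and 3. The defensin genes share near-identical copies.

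Enteroendocrine genes rose. Gcg, which encodes proglucagon, rose from 17.0 ± 0.853 to 43.9 ± 1.34 RPKM (limma, adjusted p = 2.27e-06). The cholecystokinin gene Cck rose from 67.4 ± 2.74 to 124 ± 4.49 RPKM, and the tachykinin gene Tac1 by 0.73 ± 0.07 on the log2 scale. Of 17 tested (21 listed), 10 were higher, 1 lower and 6 not past the threshold (10 higher and 1 lower adjusted over the list alone). The median over the list was 0.34 (camera, adjusted p = 0.0108; adjusted p = 0.321 with an estimated correlation). The member that fell was Neurog3, the transcription factor of enteroendocrine progenitors, from 17.7 ± 0.781 to 10.6 ± 2.78 RPKM. Enterocyte genes went both ways. Krt20, a keratin of differentiated surface cells, rose from 39.6 ± 9.84 to 74.8 ± 12.3 RPKM (limma, adjusted p = 0.00376). The amino acid transporter gene Slc6a19 and the aminopeptidase gene Anpep rose from 5.93 ± 0.656 to 12.3 ± 0.365 RPKM and from 140.1 ± 3.75 to 209 ± 9.84 RPKM. The alkaline phosphatase gene Alpi fell from 324 ± 9.57 to 247 ± 22.3 RPKM (limma, adjusted p = 0.00217), as did the apolipoprotein genes Apoa4 (from 431 ± 41.8 to 230.3 ± 16.6 RPKM) and Apoc3 and the meprin gene Mep1a. Fabp2 was at 141 ± 19.3 RPKM in control and 141 ± 25.8 in DM-aKG (limma, adjusted p = 0.953), but without control replicate 2 and DM-aKG replicate 1 it was lower by limma (log2 fold change -0.27, adjusted p = 0.00159). Of 28 enterocyte genes, 12 were higher, 4 lower and 12 not past the threshold (12 higher and 5 lower adjusted over the list alone), with a median of 0.14. The list did not pass (camera, adjusted p = 0.218); it did without control replicate 1 (camera, adjusted p = 0.0495). Without control replicate 2 and DM-aKG replicate 1, 12 higher and 11 lower enterocyte genes were called, with a median of 0.05. Of the tuft cell list only the gene Avil passed the filter, at 0.980 ± 0.173 RPKM in control and 7.56, 1.94 and 1.56 in the DM-aKG libraries (limma, adjusted p = 0.0516). It was higher without DM-aKG replicate 1 (limma, adjusted p = 0.00445) or replicate 3 (0.0248).

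Genes known from the fetal intestine and from regenerating epithelium rose together. All 10 that passed the filter, of 18 listed, were higher (10 higher and 0 lower adjusted over the list alone). Their median log2 fold change was 1.92 (camera, adjusted p = 2.16e-06; adjusted p = 0.0663 with an estimated correlation). Besides Anxa1, Anxa3 rose from 18.0 ± 0.728 to 73.9 ± 1.76 RPKM, Il1rn, which encodes the interleukin 1 receptor antagonist, from 6.87 ± 0.681 to 34.9 ± 1.72 RPKM, and the stem cell antigen gene Ly6a from 8.62 ± 1.89 to 62.2 ± 2.75 RPKM. Areg, which encodes the EGF receptor ligand amphiregulin, rose from 53.1 ± 4.75 to 189.5 ± 3.64 RPKM.

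**Figure D3:**
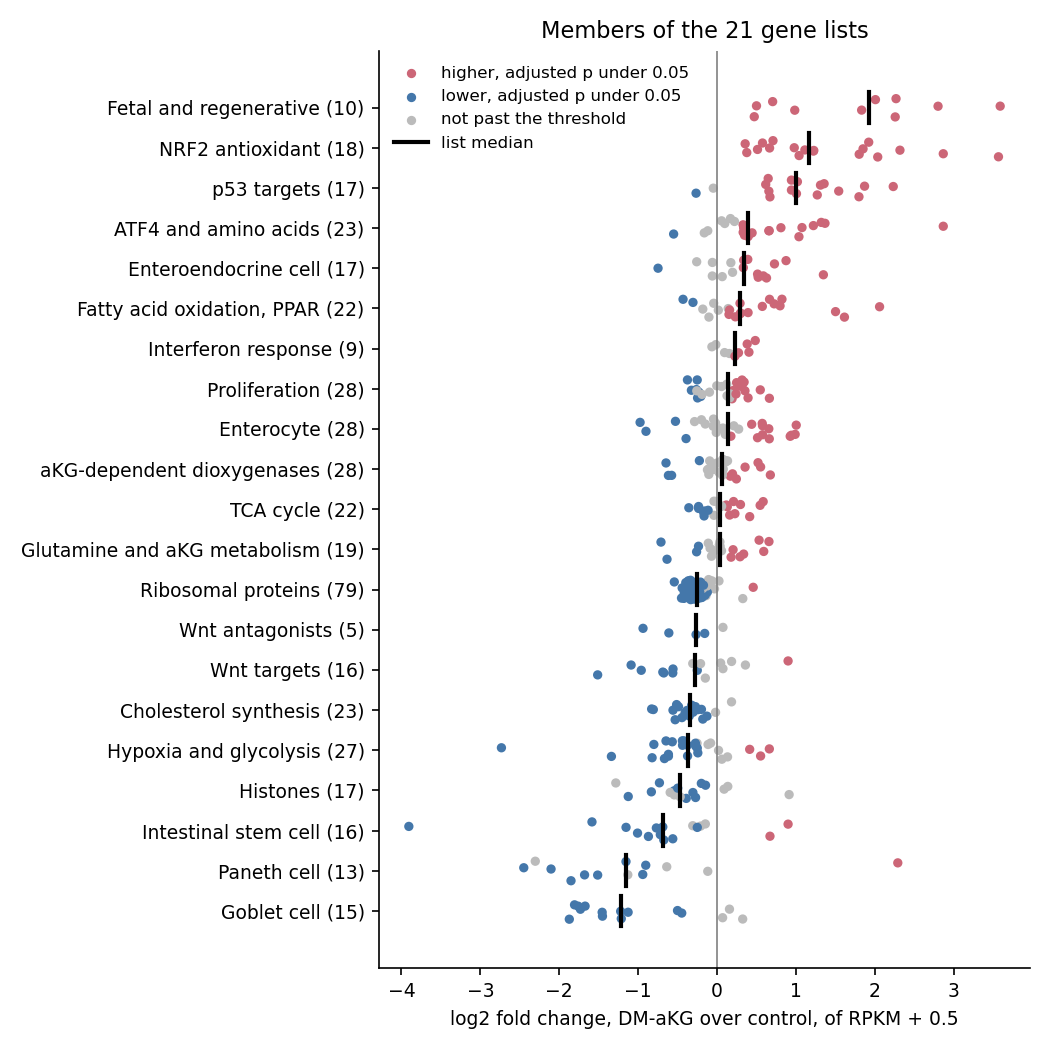
Log2 fold change (DM-aKG over control, of RPKM + 0.5) of every tested member of the gene lists with at least 5 tested genes; each point is a gene, coloured by its limma call, the black bar is the list median and the number in brackets the genes tested. Fetal and regenerative genes have the highest median (1.92) and goblet cell genes the lowest (-1.22).

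Targets of the antioxidant transcription factor NRF2 rose, with all 18 higher (18 higher and 0 lower adjusted over the list alone) and a median log2 fold change of 1.17 (camera, adjusted p = 6.92e-11; adjusted p = 0.287 with an estimated correlation). Besides Nqo1 and Slc7a11, these included the glutathione synthesis gene Gclc (from 16.8 ± 0.672 to 64.9 ± 0.879 RPKM; limma, adjusted p = 3.26e-07), the glutathione transferase gene Gsta3 (from 33.7 ± 0.497 to 119 ± 3.53 RPKM) and the malic enzyme gene Me1 (from 11.1 ± 0.599 to 57.4 ± 3.54 RPKM). Targets of p53 rose too. Among 17, 15 were higher, 1 lower and 1 not past the threshold (15 higher and 1 lower adjusted over the list alone). The list median was 1.01 (camera, adjusted p = 7.09e-07; adjusted p = 0.0663 with an estimated correlation). Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 64.4 ± 7.35 to 167 ± 33.9 RPKM, Ccng1 from 74.0 ± 2.76 to 179 ± 4.15 RPKM and Zmat3 from 10.6 ± 0.416 to 27.0 ± 0.803 RPKM. Plk2 rose from 4.75 ± 0.391 to 17.7 ± 0.828 RPKM, while Btg2 fell from 31.1 ± 0.111 to 25.7 ± 0.468 RPKM. Of 23 genes of the ATF4 response to amino acid shortage, 16 were higher, 1 lower and 6 not past the threshold (17 higher and 1 lower adjusted over the list alone). The median over the list was 0.39 (camera, adjusted p = 3.86e-04; adjusted p = 0.406 with an estimated correlation). Examples were the serine synthesis gene Psph (from 16.1 ± 0.603 to 28.6 ± 2.09 RPKM), the amino acid transporter subunit gene Slc3a2 (from 36.5 ± 3.10 to 85.8 ± 7.85 RPKM) and Trib3 (from 14.1 ± 5.83 to 34.2 ± 0.397 RPKM). The member that fell was Stc2, from 27.5 ± 8.05 to 18.2 ± 1.97 RPKM. Slc7a11 stands in both the NRF2 and the ATF4 list.

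Genes of hypoxia and glycolysis fell, 18 of 27 tested (3 were higher, 18 lower and 6 not past the threshold; 3 higher and 19 lower adjusted over the list alone). Their median log2 fold change was -0.37 (camera, adjusted p = 5.32e-04; adjusted p = 0.414 with an estimated correlation). Pdk1, a kinase that shuts pyruvate out of the TCA cycle, fell from 60.5 ± 3.47 to 40.6 ± 0.706 RPKM (limma, adjusted p = 8.76e-05), and the HIF prolyl hydroxylase gene Egln1 from 38.5 ± 3.09 to 24.4 ± 1.97 RPKM. Of the glycolytic genes, Pgk1 fell from 1121 ± 44.9 to 828 ± 75.3 RPKM, Pkm from 942 ± 17.6 to 727 ± 5.47 RPKM and Gapdh from 119 ± 2.99 to 88.8 ± 1.88 RPKM. Gapdh has many processed pseudogenes and its level is uncertain. Slc2a1, P4ha1 and Mxi1 were higher, each with overlapping groups (log2 fold change 0.66 ± 0.24 for the glucose transporter gene Slc2a1). Ankrd37 stood at 49.5 RPKM in control replicate 2 and at 27.0 and 28.7 in the other controls. Without that library and DM-aKG replicate 1, 7 members were higher and 18 lower in the list, and under quantile normalization 0 higher and 15 lower. The list median was smaller in size in these settings, at -0.24 and -0.25.

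Cholesterol synthesis genes fell as a group by small amounts. Of 23 tested, 0 were higher, 21 lower and 2 not past the threshold (0 higher and 21 lower adjusted over the list alone). The list median was -0.34 (camera, adjusted p = 5.58e-08; adjusted p = 0.154 with an estimated correlation). The sterol sensor gene Insig1 fell from 282 ± 3.93 to 159 ± 6.54 RPKM, the farnesyl diphosphate synthase gene Fdps from 233 ± 3.54 to 161 ± 4.46 RPKM and the reductase gene Dhcr7 from 53.2 ± 1.31 to 36.0 ± 1.37 RPKM. Fatty acid oxidation genes and PPAR targets rose. Of 22 tested, 15 were higher, 2 lower and 5 not past the threshold (15 higher and 2 lower adjusted over the list alone). The median over the list was 0.29 (camera, adjusted p = 0.00646; adjusted p = 0.321 with an estimated correlation). The lipase inhibitor gene Angptl4 rose from 9.70 ± 0.427 to 30.9 ± 4.35 RPKM and the pantetheinase gene Vnn1 from 1.65 ± 0.265 to 8.43 ± 1.03 RPKM. Acadm and Ppara fell, from 43.2 ± 0.767 to 34.8 ± 0.366 RPKM and from 8.20 ± 0.222 to 5.95 ± 0.257 RPKM.

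Genes that handle α-ketoglutarate itself went both ways, and their lists did not pass camera. Of 22 TCA cycle genes 9 were higher, 7 lower and 6 not past the threshold (9 higher and 7 lower adjusted over the list alone; camera, adjusted p = 0.791). Rescaling to an equal sum per library gave 9 higher and 4 lower, and median centring 6 higher and 7 lower. Ogdh, the α-ketoglutarate dehydrogenase gene, rose from 42.5 ± 1.55 to 64.1 ± 5.96 RPKM and Pdhb from 52.0 ± 0.775 to 76.1 ± 0.903 RPKM, while Pdha1 fell from 181 ± 3.37 to 141 ± 5.81 RPKM. Of 19 genes of glutamine and α-ketoglutarate metabolism 7 were higher, 4 lower and 8 not past the threshold (7 higher and 4 lower adjusted over the list alone; camera, adjusted p = 0.744). Glutamate dehydrogenase, Glud1, rose from 47.3 ± 1.30 to 68.6 ± 1.60 RPKM and alanine transaminase, Gpt2, from 7.88 ± 0.306 to 12.1 ± 0.217 RPKM. Among those lower were the ornithine aminotransferase gene Oat (from 807 ± 28.0 to 521 ± 36.7 RPKM), Slc1a5 and Slc38a2. Medians of these lists were 0.04 and 0.04. The test that does not compare a list with other genes called both as higher (fry, adjusted p = 0.0149 and 0.00266). Of 28 dioxygenases that use α-ketoglutarate as a substrate, 7 were higher, 4 lower and 17 not past the threshold (6 higher and 4 lower adjusted over the list alone; median 0.06; camera, adjusted p = 0.889). This balance depended on the setting, with 5 higher and 7 lower under median centring, 5 higher and 8 lower under quantile normalization, and 13 higher and 6 lower without control replicate 2 and DM-aKG replicate 1. The histone demethylase genes Kdm7a and Kdm5c rose, from 5.34 ± 0.405 to 8.82 ± 0.402 RPKM and from 12.1 ± 0.386 to 15.6 ± 0.731 RPKM. Those lower were Kdm2b, Kdm3a, Egln1 and Plod1. The dioxygenase list shares 5 tested genes with the hypoxia list, Kdm3a and Egln1 among them, so these are counted in both. Tet2 and Tet3, which encode DNA hydroxylases, were at 2.45 ± 0.145 and 10.9 ± 0.644 RPKM in control and 2.61 ± 0.0666 and 11.1 ± 0.197 in DM-aKG (limma, adjusted p = 0.370 and 0.719).

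Proliferation genes also divided. Mki67, a marker of cycling cells, rose from 35.6 ± 0.652 to 46.9 ± 4.44 RPKM (limma, adjusted p = 0.00177), as did Top2a (from 59.7 ± 1.20 to 76.4 ± 3.14 RPKM). The mitotic kinase gene Aurka (from 20.3 ± 0.406 to 29.9 ± 0.857 RPKM) and Rrm2 (from 44.2 ± 0.0850 to 70.3 ± 2.44 RPKM) rose too. The genes of the replicative helicase fell, Mcm6 from 29.8 ± 1.11 to 22.9 ± 1.25 RPKM and Mcm3 from 24.6 ± 1.26 to 19.5 ± 0.770 RPKM. Of 28 tested, 12 were higher, 7 lower and 9 not past the threshold (12 higher and 8 lower adjusted over the list alone), with a median of 0.14, and the list did not pass (camera, adjusted p = 0.475), though it did as higher by the other list test (fry, adjusted p = 0.0210). Without control replicate 2 and DM-aKG replicate 1, 12 higher and 11 lower proliferation genes were called. Ribosomal protein genes fell by small amounts. Among 79, 1 was higher, 65 lower and 13 not past the threshold (2 higher and 68 lower adjusted over the list alone). Their median log2 fold change was -0.26 (camera, adjusted p = 7.74e-12; adjusted p = 0.406 with an estimated correlation). Rpl37a fell from 516 ± 28.5 to 385 ± 7.28 RPKM and Rps4x from 1546 ± 45.5 to 1181 ± 44.1 RPKM, while Rps27l, also a p53 target, rose from 127 ± 2.18 to 174 ± 7.68 RPKM. Under quantile normalization 35 of the 79 were lower, with a median of -0.12, and processed pseudogenes of these genes make single values uncertain. The ribosomal RNA precursor Rn45s was at 1599, 2795 and 2856 RPKM in the controls and at 1439, 1621 and 956 in the DM-aKG libraries. Of 17 histone genes that passed the filter, of 104 listed, 0 were higher, 10 lower and 7 not past the threshold (0 higher and 10 lower adjusted over the list alone). The list median was -0.47 (camera, adjusted p = 0.00314; adjusted p = 0.321 with an estimated correlation). The members that fell were mostly replacement variants, whose transcripts carry a poly(A) tail, such as H2afv (from 26.6 ± 1.01 to 15.9 ± 1.77 RPKM), H3f3a (from 173 ± 9.90 to 119 ± 9.39 RPKM) and the linker histone gene H1f0 (from 151 ± 3.05 to 85.9 ± 18.1 RPKM).

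Of 9 tested interferon response genes (25 listed), 5 were higher, 0 lower and 4 not past the threshold (5 higher and 0 lower adjusted over the list alone), with a median of 0.23, and the list did not pass (camera, adjusted p = 0.0770). It did without control replicate 3 (camera, adjusted p = 0.0466) and by the other list test (fry, adjusted p = 0.00199). Among the genes that rose were Irf7 (from 4.83 ± 0.552 to 6.92 ± 0.333 RPKM), Bst2, Ddx58 and Ifih1. The other listed interferon genes, Isg15, Ifit1 and Rsad2 among them, lay below the filter, none above 0.77 RPKM in any library. These were not tested and went both ways. Ifit2 and Oasl2, for example, were lower in every DM-aKG library than in every control, and Rsad2 and Ddx60 were higher. Markers of cells that epithelial organoids should lack were near the floor. Of 15 fibroblast and muscle markers, Vim alone passed the filter and rose from 2.83 ± 0.150 to 4.34 ± 0.589 RPKM, and the others reached at most 0.82 RPKM in any library. Of 15 immune markers, Cd14 rose from 1.47 ± 0.101 to 2.75 ± 0.0896 RPKM and Cd68 was at 0.837 ± 0.0902 and 1.69 ± 0.739 RPKM (limma, adjusted p = 0.0523). The latter difference was past the threshold without DM-aKG replicate 1 (limma, adjusted p = 2.37e-04). The other immune markers reached at most 1.23 RPKM. None of 11 endothelial and glial markers passed the filter, and they reached at most 0.9 RPKM. Genes encoded by mitochondrial DNA were not analysed here.

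Across the lists, 15 of the 21 tested passed camera with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.0663 and 3 lists had an unadjusted p under 0.05. The list medians had the same sign under the 3 other scalings in 22 of the 24 lists with a tested member, the exceptions being the TCA cycle and the glutamine lists, whose medians lay near 0.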

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

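Leaving out control replicate 2 and DM-aKG replicate 1 together was chosen after the data were seen and gave 3722 higher and 3279 lower genes; the other settings were fixed before. The count of higher genes ran from 2689 to 3674 and that of lower genes from 2059 to 3188 when a single library was left out, with 15 to 16 lists past camera; no such count moved by more than 1.5 times. A fold change of at least 1.5 left 764 higher and 533 lower genes, because most changes were smaller. With an estimated correlation 0 lists passed in place of 15. The other list test, fry, which does not compare a list with other genes, called 19 lists. Array weights gave 4149 and 3563 genes, quantile normalization 2861 and 3190, and rescaling to an equal sum 3809 and 2252. The values gave no sign that replicate numbers pair the samples, as deviations of same-numbered libraries correlated at -0.08, -0.11 and 0.01. With 3 libraries per group a pairing cannot be excluded. The replicate block gave 3206 higher and 2542 lower genes and 15 lists, and 2 named genes gained a call with it. Named genes kept direction and side of the threshold in 1446 gene and setting pairs, lost the call in 5 (Defa30) and gained it in 14 (Avil, Cd68 and Fabp2). Lists did so in 377 pairs, lost the call in 16 and gained it in 6. In both counts a change of direction was taken as kept where neither fit passed the threshold. No list reversed with either fit past the threshold. The cause of these changes was not tested. At a length of 1 kb, genes under 1 RPKM rest on at most about 34.2 reads per library, and longer genes on more. Changes of 0.25 on the log2 scale were called in 26.5% of simulated cases, where 10506 of 10698 genes were unchanged. The share may differ in the real data, where far more genes were called, but a gene not past the threshold may still have changed by that much.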

Other observations

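Tests on the Paneth and secretory genes, and all family results, were chosen only after the values were seen. Beyond the lists fixed in advance, the 2 metallothionein genes, which bind zinc and copper, were among the most abundant transcripts and fell: Mt1 from 3635 ± 129 to 824 ± 35.3 RPKM and Mt2 from 3119.8 ± 84.3 to 713 ± 15.6 RPKM (mean ± SD, n = 3 per group). They fell by 2.14 and 2.13 on the log2 scale (limma, adjusted p = 5.96e-07 and 4.22e-07). Among 321 families of genes with a common symbol stem, 10 passed camera with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.976; 2 families had an unadjusted p under 0.05). All 7 tested S100a genes, which encode calcium-binding proteins, were higher (median log2 fold change 1.29; camera, adjusted p = 0.00215), with S100a6 from 29.4 ± 1.24 to 188 ± 12.5 RPKM. All 6 tested keratin genes were higher (median 0.88; camera, adjusted p = 0.0230), among them Krt8 from 831 ± 21.5 to 1519.5 ± 271 RPKM and Krt19 from 512 ± 3.25 to 924 ± 89.1 RPKM. Annexin genes were higher in 11 of 12 cases, glutathione transferases of the Gstm group in 6 of 7, proteasome subunits of the Psmd group in 12 of 14 and TNF receptor genes (Tnfrsf) in 9 of 12, with 1 lower. Of 259 zinc finger genes named Zfp, 119 were lower and 17 higher (median -0.19; camera, adjusted p = 2.50e-07); the Rpl and Rps stems and the Defa stem made up the rest. The medians of these families kept their sign under the 3 other scalings. Families were formed from all tested genes, so several share members with the lists fixed in advance and are not independent of them. Examples are Anxa1, Krt20, Gstm1 and genes of the Rpl, Rps and Defa stems. The Gstm and Zfp genes have close copies, so single values are uncertain.

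Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split, 1 of the 10, gave 3354 higher and 2679 lower genes and the highest of the others 0 and 0; for lists past camera with the preset correlation the real split gave 15 and the highest of the others 13. Each of the other splits put libraries of both treatments in each group. Part of the difference between treatments thus entered the spread within groups, and part stayed in the contrast. Few gene calls follow from the wider spread alone, while lists can pass on the part that stayed. The splits therefore cannot show what libraries without a treatment effect would give.

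Ribosomal protein transcripts fell in 65 of 79 cases, with a median log2 fold change of -0.26. A scaling of whole libraries, or a drift of abundant transcripts, is argued against in part by 10000 random lists of other genes, matched on mean expression. With the ribosomal list itself counted among them, the share with a median as low was 2.00e-04. The middle 95% of the matched medians ran from -0.18 to 0.03, and abundant genes as such may account for part of the fall. Removing the trend on transcript length, GC content and abundance, fitted on the other genes, left a median of -0.17. The 25th to 75th percentile ran from -0.23 to -0.09, and all 79 had a length and GC content. The trend itself explained 1.5% of the variance of the log2 fold changes in those other genes. What stays open is how far the size holds, since quantile normalization gave -0.12, and whether the genes moved together for another reason: their estimated correlation between libraries within groups was 0.765, so they count as few independent genes.

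In DM-aKG replicate 1 the median position of the 13 Paneth genes was 0.490 on the RPKM scale (25th percentile 0.412), with the other treated libraries at 0 and the controls at 1, and 3 genes (Defa3, Defa21 and Ang4) lay beyond the controls. Mixture with control RNA would place all genes alike, but the median over the 18 NRF2 genes was 0.174, with a 75th percentile of 0.303, below the 25th of the Paneth genes. Medians over called members of the other lists ran from -0.312 (proliferation) to 0.350 (ribosomal proteins), with p53 targets at 0.0631, stem cell genes at 0.232 and histones at 0.317, so some lists lay part of the way to the controls and others did not. Depth is argued against, as replicate 1 had 1.04 times the mean estimated depth of the other treated libraries. A culture that held more Paneth cells when it was treated, or responded later, may explain the pattern, and neither was tested.

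Of the tested genes, 12 of 15 goblet and 8 of 13 Paneth genes were lower and 10 of 17 enteroendocrine genes higher, though none of the 3 lists passed camera with an estimated correlation (adjusted p = 0.321, 0.406 and 0.321). Equal loss of the whole secretory lineage would lower all of them, and is argued against only by the pattern itself: the 25th percentile of the enteroendocrine log2 fold changes (0.06) exceeded the 75th percentile of the goblet genes (-0.48) by 0.54. Without control replicate 2 and DM-aKG replicate 1, 100% of the calls of each list were made again in the same direction, so the calls did not need these libraries. For goblet and Paneth genes this tests little, because DM-aKG replicate 1 lay nearer the controls than the other treated libraries. Leaving both libraries out moved the goblet median from -1.22 to -1.38 and the Paneth median from -1.15 to -1.62. A loss of part of the lineage stays open, since Atoh1 and Neurog3, transcription factors of its progenitors, fell. The hypothesis that DM-aKG may act differently on secretory cell types stays open too, beside a change of expression within cells, since bulk RNA does not count cells.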
